A study of Mus musculus with 18 samples.

How the data were processed

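Ribosomal RNA was removed from total RNA and strand-marked libraries were sequenced on an Illumina NextSeq, per the labels' protocols. The authors mapped the reads to the mouse genome GRCm38 (mm10) with CLC Genomics Workbench, per the labels; the annotation release and the strand setting of counting were not given in the sources used here. Each deposited table covers 1 tissue and 41457 genes. It holds whole-number counts of exon, unique exon, intron and exon-exon reads for each library, which the authors deposited without normalization. The authors also deposited RPKM values, counts scaled by exon length and by all mapped reads, and a p-value, a false discovery rate and a fold change per gene of their own comparison. Another 309 columns of per-sample values were not used.

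Wild type and knockout libraries were grouped by the labels, 3 per group in 3 tissues. Mapped reads per library, worked out from the RPKM values, were 39.2M to 49.0M, exon reads 16.79M to 24.05M and intron reads 18.9M to 26.7M (M, 1e6 reads), 45.2 to 60.3% of the reads in genes. A few ribosomal and 7S RNA genes took 12.3 to 16.2% of the exon reads. No pair of libraries in a group agreed within sampling noise, with chi-square per degree of freedom of 4.51 to 19.4.

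Counts of exon reads were tested with edgeR 4.0.16 in R 4.3.3, using TMM scaling factors (0.969 to 1.02), the filterByExpr filter, a robust quasi-likelihood fit and Benjamini-Hochberg adjustment at 0.05, two-sided. Each tissue had its own fit with 4 residual degrees of freedom. The common biological coefficients of variation were 0.119 in whole brain, 0.132 in cortex and 0.113 in cerebellum. A fit of all 18 libraries with tissue and genotype gave the average effect, and a fit with 6 groups gave the differences between tissues. Standard errors were derived from the coefficient and its F statistic. Fold changes are knockout over wild type on the log2 scale, and group levels in CPM use TMM-scaled library totals. Adjusted p-values are from edgeR unless another test is named.

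Before the data were examined, 44 gene lists, the tests, the alternatives and the rule for named genes were fixed. The lists hold 894 genes, of which 7 symbols had no row in the tables, and 1 list had too few members in cortex. Lists were tested with camera from limma 3.58.1 at a preset correlation, with an estimated correlation and fry beside it. Of the list calls, only that of G2 and M phase genes in cerebellum held with an estimated correlation. The named genes were the Prmt family and, per tissue, the 8 largest rises and 8 largest falls. These came from called genes with an average log2 CPM of at least 1 and no overlap between groups, without predicted, clone-named, pseudogene and sex-linked genes. Added to these were up to 3 members of each list with at least 2 calls, at most 30 per tissue, the 10 genes called in all 3 tissues whose largest p-value was smallest, and the 5 smallest p-values per contrast between tissues. A gene named outside this rule is said to be so, or belongs to a count of 5 or fewer.

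The alternatives were other scaling, DESeq2 1.42.0, limma on RPKM and with voom, other filters, covariates and each library left out. Gene positions were taken from the deposited tables and written from base 1. Of the 41457 gene IDs 41434 were in GENCODE, with the same position for 40808, and that annotation gave gene types and overlaps. On simulated data with 200 changed genes, the cerebellar fit over 17553 genes recovered 53.7% of 1.5-fold, 82.1% of 2-fold and 93.9% of 4-fold changes, and 10% of its calls were false. In whole brain (18038 genes) the shares were 58.2, 88.1 and 100%, and in cortex (16727 genes) 41.8, 70.1 and 92.4%, with 7.87 and 9.33% of calls false. The authors' deposited table called 193, 457 and 1193 genes at the same threshold in whole brain, cortex and cerebellum, of which 141, 302 and 1083 were also called here, all in the same direction.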

Results

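RNA was sequenced from brains of newborn mice (postnatal day 0) that lacked Prmt1 in the central nervous system, and from control mice of the same strain, called wild type, that carried the floxed Prmt1 alleles without Cre. Prmt1 encodes the enzyme that places most of the asymmetric dimethylation on protein arginines. The knockout carried these alleles with a Cre recombinase under the Nestin promoter, which is active in neural progenitors. Cre and the deletion came together in every knockout library, so an effect of Cre itself cannot be told apart from that of the deletion. Whole brain, cortex and cerebellum were each sampled in 3 wild type and 3 knockout libraries, 18 libraries in all. Exon reads per library ranged from 16.79M to 24.05M (M, 1e6 reads), and between 25010 and 26580 genes had at least 1 read. Whether the libraries came from separate animals was not given in the sources used here. P-values of single genes thus measure the spread between these libraries, while overlap and list tests also rest on genes as units.

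Prmt1 (ENSMUSG00000109324, GRCm38 chromosome 7, 44975989 to 44986568, protein coding) was lower in every knockout library than in every wild type library of its tissue. In whole brain it measured 113.1 ± 5.08 CPM (exon reads per 1e6 TMM-scaled exon reads; SD, n = 3) in wild type and 79.3 ± 4.27 in the knockout. In cortex the levels were 126.5 ± 11.3 and 79.5 ± 2.63 CPM, and in cerebellum 102.6 ± 1.90 and 67.2 ± 1.36 CPM (SD, n = 3 each). The log2 fold changes were -0.51 (SE 0.067, adjusted p = 0.000466) in whole brain, -0.67 (SE 0.083, adjusted p = 0.000592) in cortex and -0.61 (SE 0.063, adjusted p = 8.66e-06) in cerebellum. In whole brain the call was lost with labelled sex as a covariate (log2 fold change -0.44). That covariate sets the knockouts against wild type replicate 3 alone, the only wild type library labelled female. With the level of Xist as a covariate the call was kept (-0.52, adjusted p = 0.00652). The exon count spans the whole gene, so the deleted part was not isolated, and cells outside the Nestin lineage keep the gene. Reads across exon junctions of Prmt1 fell further, by 0.84, 0.89 and 0.89 on the log2 scale in whole brain, cortex and cerebellum. None of the other 8 family members tested (Prmt2, Prmt3, Carm1, Prmt5, Prmt6, Prmt7, Prmt8 and Prmt9) passed the threshold over all genes in any tissue. Adjusted over the list alone, 3 members fell in cortex, Prmt1, Prmt3 and Prmt7, and 1 rose, Prmt9, while in whole brain and cerebellum 1 fell, Prmt1. The nearest over all genes was Prmt3 in cortex, with a log2 fold change of -0.41 (SE 0.11, adjusted p = 0.0598).

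**Figure D1:**
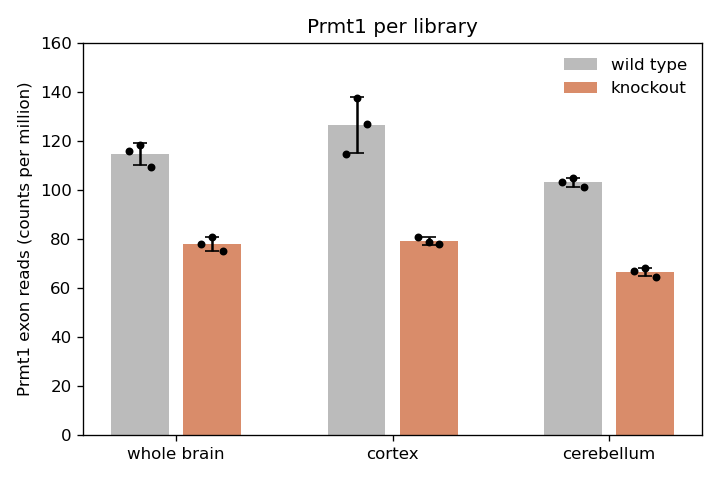
Prmt1 exon reads in CPM (vertical axis) by tissue and genotype (horizontal axis). Points are single libraries, bars the mean and whiskers the SD of 3 libraries; each is scaled by its library total alone, and the 3 knockout cerebella lie at 64.8 to 68.3 against 101.2 to 104.9 in wild type.

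Levels per library in this paragraph are scaled by library totals alone. The labels of sex were compared with the sex-linked genes, Xist from the inactive X chromosome and Ddx3y from the Y chromosome. Knockout whole brain replicate 3, labelled female, had 1.75 CPM of Xist and 42.5 CPM of Ddx3y, while the other 2 knockout whole brain libraries had 1386 and 1506 CPM of Xist. Wild type cortex replicate 1, labelled male, had 2407 CPM of Xist and 0.053 CPM of Ddx3y. The remaining 16 libraries had levels that matched their labels. By these genes the wild type whole brains were 2 males and 1 female and the knockout whole brains 2 females and 1 male, so sex and genotype overlap in part in whole brain.

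Of 30 genes of the G2 and M phases tested in the cerebellum, 28 fell and 0 rose, with a median log2 fold change of -0.60. Top2a, the topoisomerase that untangles replicated DNA, went from 190 ± 8.54 to 130.8 ± 0.77 CPM (SD, n = 3). Tpx2 and Cenpf, which act at the spindle and the kinetochore, had log2 fold changes of -0.71 (SE 0.082) and -0.58 (SE 0.067). Adjusted over the list alone, 29 fell. The list stood apart from other genes with adjusted p = 2.94e-40 in camera, and with adjusted p = 0.0215 with an estimated correlation. Of 16 replication-dependent histone genes 6 fell, 10 adjusted over the list alone, with a median of -0.55; Hist1h1d and Hist1h2bc each had a log2 fold change of -0.69. That list's camera adjusted p of 3.8e-13 became an adjusted p = 0.311 with an estimated correlation. Among 30 S phase genes 7 fell, 8 adjusted over the list alone, among them Uhrf1 (-0.58), Rrm1 (-0.42) and E2f1 (-0.59). The camera adjusted p was 0.000598, and adjusted p = 0.387 with an estimated correlation.

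Of 26 p53 targets tested in the cerebellum 12 rose, with 13 rising and 1 falling when adjusted over the list alone. The median log2 fold change was 0.32. Phlda3, a repressor of Akt signalling, rose from 3.41 ± 0.35 to 13.02 ± 1.42 CPM (SD, n = 3), a log2 fold change of 1.93 (SE 0.18, adjusted p = 2.22e-06). Cdkn1a, which encodes the cell cycle inhibitor p21, rose from 39.0 ± 2.54 to 64.9 ± 3.22 CPM, and Ccng1 had a log2 fold change of 0.96 (SE 0.11). The long noncoding RNA Trp53cor1 had a log2 fold change of 1.73, but only 13.1% of its exon reads were unique. The list had a camera adjusted p of 5.23e-11, adjusted p = 0.0555 with an estimated correlation and adjusted p = 0.00273 with fry. Of 30 RNA-binding proteins known as arginine methylation substrates, 11 fell and 0 rose, with 11 falling and 1 rising adjusted over the list alone. They included Khdrbs1 (log2 fold change -0.39, SE 0.058), Hnrnpa3 (-0.33, SE 0.056) and the splicing factor Srsf1 (-0.39, SE 0.070). The median was -0.07, with a camera adjusted p of 0.000265 and adjusted p = 0.311 with an estimated correlation. In whole brain 1 gene of this list rose and 2 fell, and in cortex 0 rose and 1 fell. The list did not pass there (camera adjusted p = 0.956 and 0.378).

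Cerebellar and neuronal genes moved in both directions. Among 27 genes of the cerebellar lineage 8 fell and 3 rose, and adjusted over the list alone 10 fell and 5 rose. Reln, the secreted guidance protein of granule cells, went from 1157 ± 33.7 to 679 ± 56.8 CPM, and Zic4, a transcription factor of granule cell progenitors, from 146 ± 10.1 to 79.2 ± 6.75 CPM (SD, n = 3). Ccnd2, a cyclin of the same progenitors, had a log2 fold change of -0.50 (SE 0.064). Of 23 pan-neuronal genes 6 rose and 2 fell, 11 and 3 adjusted over the list alone, with Nefl, Nefm and Mapt at log2 fold changes of 0.39, 0.44 and 0.29. Reads of Nefl and Nefm overlap on opposite strands, and only 20.2% of the exon reads of Nefl were unique. Of 14 oligodendrocyte progenitor genes 6 fell and 1 rose, 7 and 2 adjusted over the list alone; Olig1 and C1ql1 were at -0.44 and -0.82, while Cacng4 was at 0.29, and 8.09% of the reads of C1ql1 were unique. Aldoc, an astrocyte and Purkinje cell aldolase, rose by a log2 fold change of 0.76 (SE 0.090) within an astrocyte list in which 5 genes rose and 1 fell, 7 and 2 adjusted over the list alone. Among 27 reactive astrocyte genes 4 rose, 5 adjusted over the list alone, with Sphk1 and S100a10 at 0.51 and 0.70. Of 15 MHC class I genes 4 rose, 4 adjusted over the list alone, including H2-D1 at 0.39. Of 23 cholesterol synthesis genes 2 fell, among them the demethylase Cyp51 (-0.24), and 6 adjusted over the list alone. Camera adjusted p-values were 0.0116 for the cerebellar lineage, 0.00237 for pan-neuronal, 0.00952 for oligodendrocyte progenitor, 0.0195 for astrocyte, 0.00246 for reactive astrocyte, 0.0285 for MHC class I and 0.000765 for cholesterol synthesis. With an estimated correlation they were adjusted p = 0.571, 0.311, 0.311, 0.571, 0.311, 0.387 and 0.387 in that order.

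Further lists passed in camera in the cerebellum. Activated microglia had 3 genes that rose and 1 that fell of 18 (adjusted over the list alone 4 and 1), and the excitatory neuron list 1 that rose and 7 that fell of 23 (1 and 7 adjusted over the list alone). Of 14 inhibitory neuron genes 1 rose, of 19 meningeal genes 3, of 25 microglia genes 1 and of 30 synaptic genes 2, and adjusted over the list alone 2, 3, 1 and 8. The adjusted p-values of these 6 lists were 0.0195, 0.0195, 0.0214, 0.0214, 0.0379 and 0.043. With an estimated correlation they were adjusted p = 0.387, 0.311, 0.311, 0.576, 0.311 and 0.311.

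The falls of largest size in the cerebellum by the rule for named genes were Loxl1, AW047730, Xkr5, AI849053, Slc25a34, Tst, Nanos2 and Myocd. Loxl1, a lysyl oxidase of elastic fibres (chromosome 9, 58287738 to 58313186), went from 12.0 ± 1.63 to 2.18 ± 0.61 CPM, a log2 fold change of -2.47 (SE 0.22, adjusted p = 1.63e-06). Tst, the mitochondrial thiosulfate sulfurtransferase (chromosome 15, 78399556 to 78405907), went from 19.2 ± 1.26 to 6.27 ± 0.56 CPM (SD, n = 3). AW047730 and AI849053 overlap on opposite strands of chromosome 3, so their reads may not be separate where the strand setting of counting is not given. The rises were Poln, Phlda3, Cartpt, Trp53cor1, Fam107a, Amy1, Olfr1318 and Clcn1. Cartpt, which encodes a neuropeptide precursor, rose from 6.17 ± 0.98 to 21.3 ± 3.14 CPM, and Clcn1, a chloride channel, by a log2 fold change of 1.29 (SE 0.14). Poln and Amy1 overlap Haus3 and Rnpc3 on the same strand.

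Over all 17871 genes tested in cerebellum, 1684 passed an adjusted p of 0.05 by edgeR, 737 higher and 947 lower in the knockout. Of these 521 changed by at least 1.5-fold. Leaving out wild type replicate 1, 2 or 3 or knockout replicate 3 lowered the count to 889, 1116, 1066 and 847. Of the 53 named genes called in cerebellum 48 kept their call with each library left out in turn, and Cyp51, H2-D1, Fam107a, Olig1 and Trp53cor1 lost it in 1 or more of these fits (highest adjusted p = 0.167, 0.165, 0.0777, 0.0534 and 0.0518). The Hox gene Hoxa2, a mark of hindbrain tissue, was at 3.65 CPM in wild type replicate 3 and 4.31 CPM in knockout replicate 3 and at most 0.92 CPM in the other 4 libraries, and with its level as a covariate 1597 genes passed. Ribosomal RNA and 7S RNA genes took 15.2 to 16.2% of the exon reads of the knockout cerebella and 14.7 to 14.8% in wild type, and without these genes 1693 genes passed.

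Of 15 oligodendrocyte progenitor genes tested in whole brain 4 fell (Gpr17, Pdgfra, Olig1 and Lhfpl3), 8 adjusted over the list alone, with a median log2 fold change of -0.41. The camera adjusted p was 2.06e-14, and adjusted p = 0.213 with an estimated correlation. Pdgfra, the growth factor receptor of these progenitors (chromosome 5, 75152292 to 75198215), went from 85.5 ± 5.15 to 54.4 ± 3.87 CPM (SD, n = 3). Gpr17 had a log2 fold change of -1.48 (SE 0.12), with 3.48% of its exon reads unique, and it overlaps Lims2 on the opposite strand. Bcas1, a gene of newly formed myelinating cells, had a log2 fold change of -1.32 (SE 0.21) and was the 1 member of 22 in the myelin list that fell, 3 adjusted over the list alone. Of 30 G2 and M phase genes 3 fell (Kif11, Cenpf and Cks2), 8 adjusted over the list alone, with a median of -0.29. Of 27 p53 targets 3 rose (Phlda3, Ccng1 and Eda2r), 5 adjusted over the list alone; Eda2r, a receptor of the tumour necrosis factor family, went from 1.85 ± 0.37 to 4.30 ± 0.46 CPM (SD, n = 3). Among 30 ribosomal protein genes 2 rose, Rpl10, with 15.8% of its reads unique, and Rpl3, and 3 adjusted over the list alone. Camera gave adjusted p-values of 0.0105, 1.1e-08, 0.000323 and 3.34e-06 for the latter 4 lists. With an estimated correlation they were adjusted p = 0.598, 0.0931, 0.213 and 0.494.

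Of 19 inhibitory neuron genes 3 fell in whole brain, 4 adjusted over the list alone, and the list did not pass (median log2 fold change 0.01, mean -0.03, camera adjusted p = 0.34). The 3 were the transcription factors Dlx1, Dlx2 and Sp8, which fell by 0.37, 0.45 and 0.51 on the log2 scale; reads of Dlx1 were 10.6% unique and overlap an antisense transcript. Of 30 synaptic genes 2 fell, the adhesion genes Nlgn3 by 0.34 and Nrxn3 by 0.31, with 2 falling and 1 rising adjusted over the list alone, and the list did not pass (camera adjusted p = 0.956). The 8 falls of largest size were AW047730, AI849053, Slc25a34, Gpr17, Tst, Bcas1, Cks2 and Fam69c. The 8 rises were Gp1bb, Clcn1, Eda2r, Fam107a, Pycard, Ccdc73, Phlda3 and Fgfbp3. Gp1bb and Cks2 are uncertain, with 6.39% and 26.7% of their reads unique. Clcn1 went from 6.38 ± 1.04 to 16.4 ± 4.23 CPM, Pycard, an inflammasome adaptor, from 8.29 ± 1.23 to 17.2 ± 4.06 CPM, and Fgfbp3, a binding protein of fibroblast growth factors, from 14.6 ± 1.58 to 26.5 ± 3.51 CPM (SD, n = 3). Microglia, complement, MHC class I, meningeal, reactive astrocyte, hypothalamic and midbrain lists were higher in camera (adjusted p from 0.000411 to 0.0342) and mitochondrially encoded genes lower (0.0273), with 1 member past the threshold in each of the meningeal and reactive astrocyte lists and 0 in the others. With an estimated correlation all had an adjusted p of 0.393 to 0.761.

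Of 18371 genes tested in whole brain 204 passed, 77 higher and 127 lower, and 79 of them changed by at least 1.5-fold. With library totals in place of scaling factors the split was 61 higher and 211 lower. With labelled sex as a covariate 22 genes passed, and with the level of Xist as a covariate 94. Each library left out moved the count by over 1.5 times, to 135, 61 and 116 without wild type replicates 1, 2 and 3 and to 77, 107 and 446 without knockout replicates 1, 2 and 3. Of the 41 named genes called in whole brain 22 lost their call in 1 or more of these fits. Among them were Kif11, Cenpf, Cks2, Phlda3, Ccng1, Eda2r, Olig1, Dlx1, Dlx2, Sp8, Nlgn3, Nrxn3, Rpl10, Rpl3, Fam107a, Ccdc73 and Fam69c. Prmt1, Pdgfra, Gpr17, Bcas1, Clcn1, Pycard and Fgfbp3 were among the 19 that kept their call. The hormone gene Pomc was at 18.6 to 21.9 CPM in wild type replicates 1 and 3 and knockout replicate 2 and at 0.21 to 1.37 CPM in the other 3 libraries, and with its level as a covariate 86 genes passed. Ribosomal RNA and 7S RNA genes took 13.1 to 14.6% of the exon reads of the knockout whole brains and 12.3 to 12.7% in wild type, and without these genes 209 genes passed.

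Of 21 microglia genes tested in cortex 3 rose, C1qb, Csf1r and Cx3cr1, and 10 adjusted over the list alone, with a median log2 fold change of 0.66. Csf1r, the growth factor receptor that microglia need, went from 4.67 ± 0.85 to 9.76 ± 0.56 CPM and Cx3cr1, the fractalkine receptor, from 2.44 ± 0.54 to 5.32 ± 0.60 CPM (SD, n = 3). The camera adjusted p was 3.88e-08, and adjusted p = 0.119 with an estimated correlation. All 3 genes lost their call in 1 or more fits with a library left out, with a highest adjusted p of 0.0752 for C1qb, 0.0598 for Csf1r and 0.115 for Cx3cr1. Of 13 oligodendrocyte progenitor genes 2 fell, 7 adjusted over the list alone. Pdgfra went from 46.2 ± 1.80 to 20.1 ± 4.16 CPM, and Gpr17 had a log2 fold change of -1.34 (SE 0.17). The camera adjusted p was 2.14e-09, and adjusted p = 0.282 with an estimated correlation. The p53 target list and the immediate early list each had 1 member that rose, 4 and 2 adjusted over the list alone, with camera adjusted p of 0.0195 and 0.0118 and adjusted p = 0.282 for both with an estimated correlation. The p53 target was Cdkn1a, with 4.70 ± 0.16 CPM in wild type and 8.39 ± 0.15 CPM in the knockout. None of the 30 G2 and M phase genes passed in cortex.

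Of 23 excitatory neuron genes 2 rose in cortex, 2 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.249). Slc17a7, the vesicular glutamate transporter, rose from 48.1 ± 4.31 to 79.6 ± 13.5 CPM and Lmo3, a transcriptional cofactor, from 101.0 ± 18.6 to 182.9 ± 15.8 CPM (SD, n = 3). Of 30 synaptic genes 1 rose and 1 fell, 1 and 3 adjusted over the list alone (camera adjusted p = 0.754). These were the vesicle gene Sv2b, with a log2 fold change of 0.45 (SE 0.099), and Nlgn3 at -0.40 (SE 0.071). Of 18 inhibitory neuron genes 1 rose and 2 fell, 3 and 8 adjusted over the list alone (camera adjusted p = 0.156), with Gad1 at 0.42 (SE 0.10), and Nxph1 and Prox1 at -0.55 (SE 0.11) and -0.62 (SE 0.12). The rises of largest size were Pagr1a, Poln, Sowaha, Col6a1, Htr2c, C1qb, Zfp820 and Erbb3, and the falls Nudt14, Muc19, L3hypdh, Tst, Duxbl1, BC025920, Adgrg3 and AW047730. Only Pagr1a, Poln, Nudt14, Muc19 and AW047730 of these kept their call with each library left out in turn. Pagr1a is uncertain, since 1.89% of its exon reads were unique and it overlaps its near-identical copy Pagr1b. Duxbl1 and BC025920 are uncertain for the same reason, with 7.83% and 3.83% of their reads unique.

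Of 17054 genes tested in cortex 321 passed, 120 higher and 201 lower, and 188 of them changed by at least 1.5-fold. Leaving out wild type replicate 1 or 2 or knockout replicate 1 or 3 lowered the count to 107, 129, 144 and 148. With labelled sex as a covariate, in which wild type replicate 1 is the 1 library labelled male, 109 genes passed. Of the 36 named genes called in cortex 18 lost their call in 1 or more of the leave-out fits. They were the 3 microglia genes, Gad1, Nxph1, Prox1, Sv2b, Slc17a7, Tst, Sowaha, Col6a1, Htr2c, Zfp820, Erbb3, L3hypdh, Duxbl1, BC025920 and Adgrg3. Prmt1, Pdgfra, Gpr17, Lmo3, Nlgn3 and Poln were among the 18 that kept their call.

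**Figure D2:**
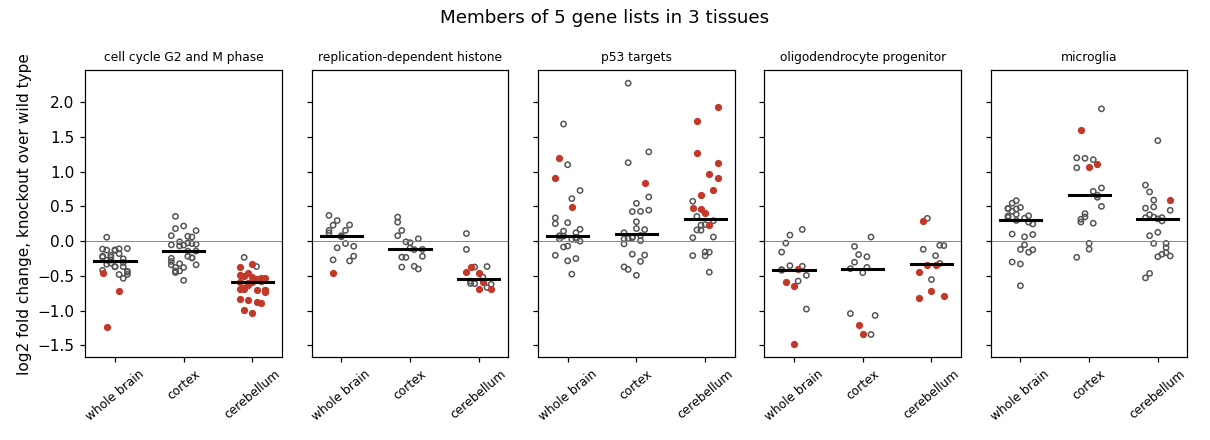
Log2 fold change of knockout over wild type (vertical axis) for the members of 5 gene lists in 3 tissues (horizontal axis). Each point is a gene, filled red where its adjusted p is under 0.05, and the line is the median; in the cerebellum the G2 and M phase median is -0.60 and the p53 target median 0.32.

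The tissues shared calls in the same direction beyond what independent lists give. Cortex and cerebellum shared 53 higher and 102 lower genes against 4.86 and 10.8 for independent lists. Whole brain and cerebellum shared 34 and 84 against 3.19 and 6.48, and whole brain and cortex 21 and 50 against 0.53 and 1.47. The largest adjusted p of the 6 one-sided Fisher exact tests was 6.08e-27. These tests count genes as independent units, so genes that change together can make the p-values too small. Tissues taken from the same animals would also share calls, and whole brain holds cortex and cerebellum. Wild type whole brain replicates 1 and 2 and knockout replicate 3 had 32.9, 34.5 and 42.5 CPM of Ddx3y, scaled by library totals alone. No cortex or cerebellum library had over 0.42 CPM, which argues against animals shared with those whole brains. Sharing stays open for the remaining libraries, cortex with cerebellum among them. Only Igfbp5 and Kif26b passed in opposite directions, in cortex and cerebellum. In all 3 tissues 59 of 16467 genes passed in 1 direction, 18 higher and 41 lower. The 10 of them whose largest p-value over the 3 tissues was smallest were Clcn1 and Fbln2, which rose, and Prmt1, Npr2, Mthfsd, AW047730, Slc2a13, D430041D05Rik, Vars and Rbmxl1, which fell. Fbln2, an extracellular matrix protein, had log2 fold changes of 0.61, 0.96 and 0.75 in whole brain, cortex and cerebellum (SE 0.090, 0.15 and 0.083). Npr2, the receptor of C-type natriuretic peptide, was at -0.59, -0.70 and -0.65, and Vars, the valyl-tRNA synthetase, at -0.48, -0.60 and -0.64. Slc2a13, a transporter of myo-inositol, was at -0.57, -0.74 and -0.91. Mthfsd and Rbmxl1 are less certain, with at most 19.3% and 29.9% of their reads unique.

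Averaged over the tissues, 2474 of 19429 genes passed, 1176 higher and 1298 lower. Prmt1 was at -0.59 (SE 0.041, adjusted p = 5.51e-10), AW047730 at -2.04 (SE 0.13) and Clcn1 at 1.24 (SE 0.10). This fit counts each library as a separate animal, which the sources used here do not give, so its p-values can be too small.

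The effect of the knockout differed between cerebellum and cortex for 136 genes, by a test of the difference itself. Those with the smallest p-values were Ccnd2, Nfia, Reln, Igfbp5 and Ak1. Ccnd2 was at -0.49 in cerebellum and 0.26 in cortex (difference -0.75, SE 0.095, adjusted p = 0.000506), and Nfia, a glial and granule cell transcription factor, at -0.63 and 0.15 (difference -0.78, SE 0.11). Between whole brain and cortex 13 genes differed, among them Rasgrp1, a Ras activator, at 0.15 in whole brain and 1.38 in cortex, and Prox1 at 0.16 and -0.62. Between whole brain and cerebellum 3 genes differed, Reln, Nav2 and Cdkn1a; Cdkn1a was at 0.05 in whole brain and 0.75 in cerebellum (difference -0.70, SE 0.12, adjusted p = 0.0445). The change of Prmt1 itself did not pass in any of the 3 contrasts, with adjusted p of 0.881, 0.758 and 0.942. The count of 136 became 77, 60, 51, 49 and 78 without wild type cortex replicates 1 and 2 and wild type cerebellum replicates 1, 2 and 3, and 208, 77, 77 and 77 without knockout cortex replicates 2 and 3 and knockout cerebellum replicates 2 and 3. The count of 13 became 5, 4 and 7 without wild type and 4, 4 and 5 without knockout whole brain replicates 1, 2 and 3, 3, 3 and 32 without wild type cortex replicates 1, 2 and 3, and 26 without knockout cortex replicate 2. The count of 3 became 1 without replicate 2 of wild type or knockout cerebellum and 5 without knockout cerebellum replicate 3. With labelled sex as a covariate 80, 5 and 0 genes differed. Whether chance gives counts like those of the 3 contrasts was not settled by other splits of the libraries, as given further below.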

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

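Tests of explanations in this part were chosen after the results were seen, except that of genes inside introns. The knockout effect differed between tissues by a test of the difference for 136 genes (cerebellum against cortex), 13 genes (whole brain against cortex) and 3 genes (whole brain against cerebellum). For cerebellum minus cortex the log2 differences were -0.75 for Ccnd2, -0.78 for Nfia, -0.67 for Reln, -0.69 for Igfbp5 and 0.81 for Ak1. For whole brain minus cortex they were -1.19 for Lypd1, -1.23 for Rasgrp1, 1.04 for Nt5dc2, 0.78 for Prox1 and -4.85 for Myo3b. For whole brain minus cerebellum they were 0.67 for Reln, 0.59 for Nav2 and -0.70 for Cdkn1a.

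Other splits of the libraries within tissues were counted for each of these. Of 100 splits, the real one included, 7 gave at least 136 genes for cerebellum against cortex (highest other 1853), 7 gave at least 13 for whole brain against cortex (highest other 151) and 18 gave at least 3 for whole brain against cerebellum (highest other 1067), so chance is not excluded for these counts by the splits. In 6 of the 6, 5 of the 6 and 9 of the 17 other splits as large, most knockout libraries kept their label in 1 tissue and most had it swapped in the other, against 47, 49 and 52 of all 99 other splits. For whole brain against cerebellum the share was about equal, but its highest other counts, 1067, 586 and 452, were all such splits. A swap in 1 tissue turns an effect shared by tissues into a difference, so the high counts point to a structure of the samples. Since these splits carry the shared effect along, they are a poor measure of chance for a difference between tissues, and chance stays open. For the average over tissues 1 of 100 splits reached 2474 genes, the real one, with 844 as the highest other. This share lies under 0.05 and argues against chance there, provided that libraries of different tissues do not share animals. Within a tissue 10 splits are too few for a share under 0.05. The real counts were 204, 321 and 1684 in whole brain, cortex and cerebellum, the highest others 12, 3 and 2, and in each 1 split, the real one, reached the real count.

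Intron reads, which the comparisons above did not use, showed a changed ratio of intron to exon reads in knockout libraries for 13 genes in whole brain (12 higher, 1 lower), 19 in cortex (16 and 3) and 71 in cerebellum (58 and 13). The genes named here were chosen after their values were seen. In all 14 genes called in at least 2 tissues the direction was shared, and 5 were called in all 3: Prmt1, Ube2ql1, Map2k2, Ccdc34 and Dnah17. Ube2ql1, a ubiquitin-conjugating enzyme, had intron reads higher by 1.05, 1.06 and 0.82 on the log2 scale in whole brain, cortex and cerebellum, with exon reads at 0.01, -0.09 and 0.06. Map2k2, the MEK2 kinase, had ratios higher by 0.74, 0.70 and 0.78. Prmt1 had ratios higher by 0.96, 0.66 and 0.75 with intron reads at 0.45, 0.00 and 0.14, none of them past the threshold.

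A higher share of unspliced RNA in whole knockout libraries would raise the ratio of most genes alike. Without scaling, the median change of the log2 ratio over all tested genes was 0.0319 in whole brain, -0.000345 in cortex and -0.0554 in cerebellum (SD over genes 0.355, 0.345 and 0.34). In the genes called higher it was 0.793, 0.757 and 0.526. These genes were chosen by a rise of the ratio, so their medians had to be higher and cannot decide. Over all tested genes the median rose only in whole brain, by 0.0319, so a rise common to most genes was small at most. This test took the place of an earlier one on the intron share of whole libraries, which did not decide. Intron and exon reads were also scaled apart in the calls, which takes a share common to all genes out of the ratio. Reads of other genes inside the introns stay open: 65.5% of the 84 called genes shared their span with another gene against 57.6% of the others (Fisher exact p = 0.0888, one-sided, odds ratio 1.39, interval 0.87 to 2.27). Of 10 splits 1 gave as many genes in whole brain, 2 in cortex and 1 in cerebellum, with highest others of 2, 24 and 9, and 10 splits are too few for a share under 0.05. An effect of the deletion on splicing stays open as untested, since the tables do not give single introns.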

How the results depend on the processing

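Unique exon reads, tables without ribosomal and 7S genes, and the levels of Xist, Pomc and Hoxa2 as covariates were chosen after seeing the data. In whole brain, cortex and cerebellum, where 204, 321 and 1684 genes passed, RLE size factors, library totals, unique reads, a CPM filter and tables without ribosomal genes stayed within 1.5 times of these counts. A minimum of 1.5-fold left 79, 188 and 521, and limma on log2 RPKM called 9, 60 and 638. DESeq2 called 373 and 576 in whole brain and cortex, no low-count filter 541 and 926, labelled sex as a covariate 22 and 109, libraries labelled female alone 30 and 107, the Xist covariate 94 and 203, and all 18 libraries in 1 fit 114 and 992. The libraries labelled female hold 1 wild type library in whole brain, assumed to vary like the knockouts, and knockout replicate 3 with the Y-linked genes of a male; in cortex they are those left without wild type replicate 1, a female by Xist. Labelled sex carries the same mismatches, and in whole brain its covariate leaves wild type replicate 3 alone against the knockouts. Limma-voom called 162 in cortex, and with the Pomc covariate 86 passed in whole brain. Each library left out gave 61 to 446, 107 to 359 and 847 to 1554 genes, and 2023 to 2533 for the average over tissues, which no alternative moved by 1.5 times.

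The labels do not say that replicate numbers pair the libraries, and correlations of same-numbered deviations were all under 0.1: -0.041, -0.13 and -0.022 in whole brain, -0.00054, 0.034 and 0.061 in cortex, and 0.079, 0.077 and 0.092 in cerebellum, where each wild type library correlated best with the knockout library of its own number. With the replicate block 714, 660 and 2316 genes passed in whole brain, cortex and cerebellum, 5 differed between whole brain and cerebellum, and shared calls were 187, 377 and 286 for whole brain with cortex, whole brain with cerebellum and cortex with cerebellum. These overlaps were 71, 118 and 155, and 24, 38 and 43 at a threshold of 0.01. The block also leaves fewer residual degrees of freedom. Its count rose in whole brain too, where all same-numbered correlations were negative, so the rise does not show that libraries are paired.

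Between cerebellum and cortex 80 genes differed with sex as a covariate and 296 by DESeq2, between whole brain and cortex 5 and 49, and between whole brain and cerebellum 0 (1230 genes had an unadjusted p under 0.05 by edgeR without the covariate) and 46. No low-count filter gave 22 and 28 for the contrasts with whole brain. Libraries left out gave 49 to 208, 3 to 32 and 1 to 5. Of the 12, 4 and 18 lists that passed in camera, 0, 0 and 1 passed with an estimated correlation. Over all lists 4, 1 and 8 passed with fry. In whole brain these were the G2 and M phase, p53 target, oligodendrocyte progenitor and Prmt family lists, and in cortex the microglia list. In cerebellum they were the G2 and M phase, p53 target, synaptic, excitatory neuron, RNA-binding protein, microglia, pituitary and oxidative phosphorylation lists. The Prmt family, pituitary and oxidative phosphorylation lists had not passed in camera. With labelled sex as a covariate 17 passed in whole brain, 14 higher and 3 lower, and only 9 of the 12 were among them; in cortex 6 passed, the 4 among them. The replicate block gave 11, 5 and 18, and RLE size factors 12, 4 and 18. Libraries left out gave 9 to 17, 4 to 6 and 12 to 25, which held 8 to 11 of the 12, 3 or 4 of the 4 and 12 to 17 of the 18. Of single lists 1 reversed: mitochondrially encoded genes in cortex, not called with all libraries (median log2 fold change 0.12, adjusted p = 0.307), were lower without wild type replicate 2 (adjusted p = 0.0293) and higher without wild type replicate 1 (0.00152) and also with labelled sex as a covariate, with a range of 0.00152 to 0.617 over libraries left out. No named gene reversed. Named genes lost their call in 247 of the runs in whole brain, 151 in cortex and 29 in cerebellum, where 782, 718 and 1066 kept their side of the threshold. In whole brain Prmt1 itself lost its call in limma on RPKM (adjusted p = 0.176) and with labelled sex as a covariate (log2 fold change -0.44). The loss with that covariate and the loss among libraries labelled female say little, for the reasons above. What moved the counts in these alternatives was not tested. The fit that tested RPKM in place of missing counts was not run because counts were given.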

Other observations

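In this part the tests on the S phase list, pituitary reads and the transgene were chosen after the results were seen. The fall of G2 and M phase genes in the knockout cerebellum, with a median log2 fold change of -0.60, was set against 3 explanations. Tissue from outside the cerebellum would lower cerebellar genes alike. The 431 genes at least 8-fold higher in wild type cerebellum than cortex had a median of -0.138. Their lower quartile of -0.53 lay above the median of the list, which argues against tissue like cortex. Tissue that shares these genes, such as hindbrain, is not covered, since they were chosen against cortex alone. Transcript length and level are argued against too, as the lowest median of 1000 matched random lists was -0.179, above that of the list. An equal loss of cells in every phase of the cycle cannot be told apart from other changes, since the S phase list had a median of -0.12 with quartiles that leave out -0.60, while the histone list had a median of -0.55 with quartiles that include it. An effect of the deletion on cell division stays open, as no test here separates it from the number of cells or from an effect of Cre itself.

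Growth hormone (Gh), chosen after its values were seen, was at 2.74, 2.25 and 2.82 CPM in the 3 knockout cerebella, 148 reads in all, and at 0, 0.059 and 0 CPM in wild type, 1 read in all. In whole brain it was at 86.1, 89.3 and 90.9 CPM in the same 3 libraries that had high Pomc, and in the other 3 at 0.73 and 2.07 CPM in knockout replicates 1 and 3 and at 0.044 CPM in wild type replicate 2. Pituitary tissue in the knockout cerebella would bring Pomc with Gh. The slope in whole brain, 0.217 CPM of Pomc per CPM of Gh (SE 0.0157), added to the wild type mean of 1.11 CPM (SD 0.133), gives 1.67 CPM of Pomc in the knockout. The mean was 1.01 CPM (SD 0.281), lower than that by more than 0.314 CPM, the spread from both SDs and the error of the slope, which argues against tissue with the Pomc of those whole brains. A wider sum over 11 genes that went with Gh in whole brain did not decide (70.9 CPM, 67.1 expected, spread 46.5), since most of it was U3 RNA genes with high levels in wild type cerebellum. A growth hormone sequence carried by the Cre transgene, as some Cre lines hold, is a candidate explanation that cannot be told apart from an effect of the deletion, since each knockout library has both and the labels name no such sequence. In cortex the mean was higher by 0.31 CPM in the knockout, with 0.30 to 0.62 CPM against 0 to 0.47 CPM in wild type, which overlap.

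Intron reads alone called 233 genes in whole brain, 280 in cortex and 878 in cerebellum. Of the genes called on exon reads that also had an intron test, 88.5, 93.4 and 92.3% had the same direction in introns. Both kinds of reads came from the same libraries, so the shared direction is no separate evidence for these calls.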
